A study of Mus musculus with 16 samples.

How the data were processed

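Poly(A) RNA was sequenced from 16 tumor cell suspensions, per the labels' protocols. 4T1 cells were implanted in the mammary fat pad (400000 cells) or under the capsule of the liver (200000 cells), tumors grew for 15 days, and excised tissue was digested with collagenase, DNase and hyaluronidase before the cells were frozen. Paclitaxel was injected into the peritoneum at 10 mg/kg, 5 times per week for 2 weeks, and control mice received saline. Digested tumor tissue holds host cells besides the carcinoma cells. The labels do not say how the 15 days of growth relate to the weeks of treatment, nor whether the untreated samples were saline controls taken at the end or tumors taken before dosing, so tumor age is not known to be the same before and after treatment.

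The submitters' processing notes name fastp, StringTie and the build GRCm38/mm10, without roles or versions. The authors deposited 3 tables, none of which names its unit, so the units were read from the values. The table of the 10 liver libraries holds FPKM, deposited by the authors with 2 decimals, with column sums of 511645 to 547765. The table of the 6 subcutaneous libraries holds TPM as deposited, with each column summing to 1000000, made from FPKM rounded to 2 decimals, since its low values are whole multiples of 1 step per column within a tolerance of 0.01. The table of the 8 untreated libraries, deposited by the authors, holds neither: its values are TPM plus a constant for each gene and batch, and 2382 genes have values below 0, down to −313.3. Differences between columns of 1 batch equal those of the TPM from the other tables within 7.8e-06. The constant is shared by pre_Liver replicates 1 to 3 and the 3 subcutaneous libraries and has the opposite sign in pre_Liver replicates 4 and 5, and it equals the gap between the liver means of the batches divided by 2, within 4.3e-06. It lifts genes such as Alb by the same amount in the subcutaneous libraries as in pre_Liver replicates 1 to 3 and lowers them in replicates 4 and 5, and it exceeds 10 TPM in size for 3110 genes. No depth or read count can be recovered from TPM or from rounded FPKM, so the depth behind each value is unknown.

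The design had assumed that the untreated table held usable normalized values. For the comparison of sites before treatment the batch constant was removed, which restored TPM for 17391 of 17523 genes, and the values as deposited were kept as an alternative. The subcutaneous response used the subcutaneous table, and the liver response the FPKM of the liver table. The difference between the responses used TPM computed over 16858 genes present in all tables. Names that a spreadsheet had turned into dates (22 in the subcutaneous and 24 in the untreated table) were left out, as was 1 name on more than 1 row, and 63 names had a hyphen restored. Mitochondrially encoded genes were not tested, as the list had no gene among those tested. Coordinates are those of the GENCODE annotation of GRCm38, counted from 1.

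Values were analysed as log2(value + 1) for genes with a mean value of at least 1 over the libraries in a fit, so fold changes of low genes are understated. Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with group as the only term, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The difference between the responses was the interaction term in 1 fit of the 4 groups. Tables were prepared with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and plots with matplotlib 3.10.9. The 56 gene lists of cell types and pathways were tested with limma's camera at a preset correlation of 0.01 when at least 4 members were tested, with adjustment over the lists of a comparison, and again with an estimated correlation, under which no list was called in any of the 4 comparisons. Several lists share members. Camera compares a list with the other genes, so a list can be called lower with a median near 0 where the median of all genes is above 0. Counts of members called are given over all genes and adjusted over the list alone. List scores per library were compared by exact two-sided permutation tests, except for the difference between the responses. No list reached an adjusted p under 0.05 in these permutation tests. The lowest was 0.0656 before treatment, 0.252 in the subcutaneous response and 0.0873 in the liver response. In the subcutaneous response none could, as the unadjusted p cannot go below 0.1 there.

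Groups, tests, gene lists, the alternatives marked as planned and the rule for named genes were fixed before the data were examined. For each comparison the text names the 6 genes with the largest rise and the 6 with the largest fall among called genes whose groups did not overlap and whose mean in the higher group was at least 5, up to 4 members of each described list in order of p, and 21 genes set in advance where tested. The non-overlap condition has no meaning for a difference of 4 groups and was not applied there. Genes named outside the rule were chosen after their values were seen: Acta1, Ifit1, the library values of Alb, and the change of Pf4 in subcutaneous tumors.

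The fits were tested on simulated data in which 200 genes were changed in 5 runs. A log2 change of 1 was recovered for 26.6% of changed genes before treatment, 45.2% in the subcutaneous response, 35.4% in the liver response and 9.8% in the difference, and a change of 2 for 65.2%, 86%, 79.6% and 54.4%. Of the genes called in these runs, 8.51%, 5.87%, 5.27% and 4.09% had not been changed. The simulation drew each gene independently, without the variation that genes share among the real libraries. These shares therefore do not give the rate of false calls in the real data. Alternatives covered the pseudocount, the filter, 3 scalings, the replicate number as a block, each library left out, the variance trend, array weights, a minimum fold change, shared fits, a hepatocyte covariate and other set tests. Count-based tests planned for the case of raw counts were not run, as the tables hold no counts.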

Results

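Gene expression was measured by RNA sequencing in tumors grown in BALB/c mice from 4T1 cells, a mouse mammary carcinoma line used as a model of triple-negative breast cancer. The series set tumors of the mammary fat pad, which the submitters call subcutaneous, beside tumors grown in the liver, and asked how each site responds to paclitaxel, a drug that stabilises microtubules and stops dividing cells in mitosis. The 16 libraries formed 4 groups, with 3 untreated (pre_SC) and 3 treated (post_SC) subcutaneous tumors and 5 untreated (pre_Liver) and 5 treated (post_Liver) liver tumors. The labels number the libraries within a group and do not say that each came from a separate mouse, so the p-values measure the spread between these libraries. Nor do they say whether the untreated tumors were taken before dosing or were saline controls of the same age, so a change after treatment includes any difference in tumor age. The deposited values were FPKM or TPM, the sequencing depth of each library is unknown, and no interval for counting error is given.

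Hepatocyte RNA varied widely among the liver libraries. Alb, the gene for serum albumin, stood between 8265 and 61440 TPM in the 5 untreated liver tumors and between 737.6 and 21970 TPM in the 5 treated ones. In the 6 subcutaneous libraries its highest value was 4.23 TPM, all on the scale of TPM over the genes shared by the 3 tables. Pairs of subcutaneous libraries of 1 group correlated at r = 0.944 to 0.979 across genes, which are not independent replicates, and pairs of liver libraries at r = 0.693 to 0.992. The closest pair, post_Liver replicates 2 and 3, differed by more than 2-fold in 0.4% of 11317 genes. Each was kept as a replicate because no counts were at hand to test the pair against sampling noise.

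Before treatment, liver tumors stood apart from subcutaneous tumors first by the transcripts of liver cells. Alb (chromosome 5, 90460897 to 90476602, GRCm38) averaged 34910 ± 22260 TPM (SD, n = 5) in liver tumors and 2.81 ± 2.12 TPM (SD, n = 3) in subcutaneous tumors, a log2 difference of 13.07 ± 0.71 (SE; limma adjusted p = 5.02e-06). Ahsg, which encodes the plasma protein fetuin-A, was higher by 12.09 ± 0.50 (SE) on the log2 scale (limma adjusted p = 1.77e-06). Apoa1 and Apoa2, apolipoproteins of high-density lipoprotein, were each higher by 11.77 ± 0.56, and the plasma serpins Serpina3k and Serpina1c by 11.63 ± 0.66 and 11.49 ± 0.58. The serpins belong to families of near-identical copies, so their values are uncertain. All 30 genes of the hepatocyte list were higher in liver tumors, also 30 when adjusted over the list alone, with a median log2 difference of 9.93 (camera adjusted p = 1.5e-34, and adjusted p = 0.221 with an estimated correlation). Its examples Hpx (hemopexin) and Fgb and Fgg (fibrinogen chains) were higher by 9.81 ± 0.23, 11.41 ± 0.30 and 11.02 ± 0.31.

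Genes of several other liver cell types were higher as well, those of the biliary epithelium not among them. Of 8 biliary genes, 2 were higher and 6 lower, the same adjusted over the list alone, and the list was not called (median −2.46; camera adjusted p = 0.954). The carcinoma epithelium list had the same median, so the biliary genes do not show whether bile duct cells differed. Cd5l was higher in liver tumors by 6.35 ± 0.27 and Clec4f, a lectin of resident macrophages, by 6.06 ± 0.33. Of 10 Kupffer cell genes, 8 were higher (8 adjusted over the list alone; camera adjusted p = 3.83e-08, and adjusted p = 0.236 with an estimated correlation). The scavenger receptor Stab2 was higher by 3.99 ± 0.28. Among 10 genes of the sinusoidal endothelium, 6 were higher and 1 lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.000628, and adjusted p = 0.546 with an estimated correlation). Lrat, the enzyme that stores vitamin A as esters, was higher by 2.48 ± 0.23. Hepatic stellate cell genes gave the same counts of 6 and 1 of 10, over all genes and adjusted over the list alone (camera adjusted p = 0.000589, and adjusted p = 0.221 with an estimated correlation). The antigen receptor chains Cd79a and Cd79b were higher by 2.81 ± 0.56 and 2.495 ± 0.44. Of 11 B cell genes, 8 were higher and 1 lower, and 10 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00011, and adjusted p = 0.809 with an estimated correlation).

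Genes of liver metabolism and plasma proteins were also higher in liver tumors. Of 16 genes that take up, oxidise or export paclitaxel, 13 were higher and 2 lower, with the same numbers adjusted over the list alone (camera adjusted p = 3e-11, and adjusted p = 0.221 with an estimated correlation). Cyp3a11, a hepatic cytochrome P450 that oxidises drugs, was higher by 9.01 ± 0.60, and the uptake carrier Slco1b2 by 7.63 ± 0.54. The drug exporters Abcb1a and Abcb1b went opposite ways, at 1.05 ± 0.27 (limma adjusted p = 0.0184) and −1.21 ± 0.44 (limma adjusted p = 0.0478). All 20 xenobiotic metabolism genes, 18 of 20 acute phase genes and 23 of 24 complement and coagulation genes were higher, each count unchanged when adjusted over the list alone. Their medians were 6.73, 7.87 and 5.95, with camera adjusted p = 3.34e-20, 1.21e-21 and 3.72e-23 and for each list adjusted p = 0.221 with an estimated correlation.

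Subcutaneous tumors were higher in genes of glucose breakdown, low oxygen and carcinoma epithelium and in 3 named matrix metalloproteinases. Crabp1, a binding protein for retinoic acid, averaged 202 ± 117 TPM (SD, n = 3) against 0.0813 ± 0.0745 TPM (SD, n = 5) in liver tumors, a log2 difference of −7.31 ± 0.43 (SE; limma adjusted p = 7.6e-06). The matrix metalloproteinases Mmp10, Mmp13 and Mmp3, which degrade collagen and other matrix proteins, were lower in liver tumors at −6.01 ± 0.49, −5.87 ± 0.60 and −5.82 ± 0.60, the granzyme Gzmf at −5.34 ± 0.52 and Lrrc15, a surface protein of activated fibroblasts, at −5.28 ± 0.23. The glucose transporter Slc2a1 was lower at −2.55 ± 0.40 and the aldolase Aldoa at −1.90 ± 0.40. Of 16 glycolysis genes, 15 were lower in liver tumors, also 15 adjusted over the list alone (list median −1.41; camera adjusted p = 0.00514, and adjusted p = 0.847 with an estimated correlation). Adm (adrenomedullin) stood at −2.38 ± 0.28. Of 18 hypoxia genes, 15 were lower and 1 higher, unchanged when adjusted over the list alone (list median −1.71; camera adjusted p = 0.0077, and adjusted p = 0.847 with an estimated correlation). Without pre_Liver replicate 2 the hypoxia list was no longer called, with a median of −1.88 and adjusted p = 0.105, within a range of 0.000168 to 0.847 over its alternatives. Cdh1 (E-cadherin) and Krt8 (keratin 8) were lower at −2.68 ± 0.57 and −1.43 ± 0.34. Of 16 carcinoma epithelium genes, 14 were lower in liver tumors and 16 adjusted over the list alone (list median −2.46; camera adjusted p = 0.00943, and adjusted p = 0.847 with an estimated correlation). This median was further below 0 than those of glycolysis and hypoxia, and that of all genes was −0.52. A smaller share of carcinoma RNA in liver tumors was not tested apart from lower expression of the glycolysis and hypoxia genes. All liver tumors came from 200000 implanted cells and all subcutaneous tumors from 400000, so site and cell number cannot be told apart.

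**Figure D1:**
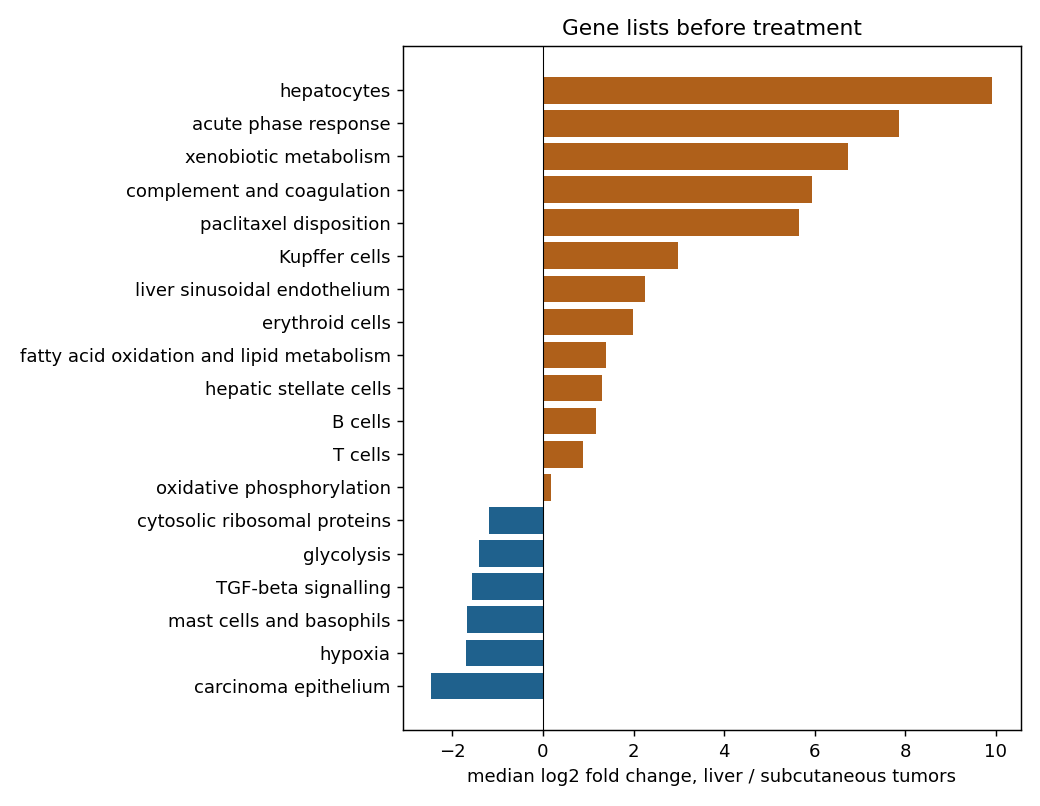
The bars give the median log2 difference between 5 liver and 3 subcutaneous tumors before treatment for each of the 19 gene lists called by camera, drawn from 0, with lists higher in liver tumors to the right. Medians ran from −2.46 for carcinoma epithelium to 9.93 for hepatocytes, and none of the 19 calls held with an estimated correlation.

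Among the immune genes set in advance, Ly6g, a surface marker of neutrophils, was higher in liver tumors by 2.90 ± 0.32 (limma adjusted p = 0.00031). It averaged 1.15 TPM in subcutaneous tumors. The score of the whole neutrophil list differed by −0.01 (exact permutation p = 0.964, and 0.982 after adjustment), so the rise of Ly6g was not shared by the list. The checkpoint receptor gene Pdcd1 was higher by 1.00 ± 0.36 (limma adjusted p = 0.0485) and the granzyme Gzmb lower at −1.58 ± 0.52 (limma adjusted p = 0.036). The call of Pdcd1 ended without any 1 of pre_Liver replicates 1 to 3 or of the 3 untreated subcutaneous libraries (adjusted p = 0.0784, 0.0586, 0.0976, 0.0935, 0.121 and 0.142, within a range of 7e-05 to 0.142 over its alternatives). That of Gzmb ended without any 1 of the 3 untreated subcutaneous libraries or pre_Liver replicate 5 (adjusted p = 0.0776, 0.0823, 0.124 and 0.0665, within 0.00885 to 0.124). Abcb1a lost its call without any 1 of the 3 untreated subcutaneous libraries (adjusted p = 0.0635, 0.0561 and 0.0699, within 1.32e-05 to 0.106), and Krt8 without pre_SC replicate 3 (adjusted p = 0.0595, within 5.31e-06 to 0.0595). Abcb1b lost its call without any 1 of 7 of the 8 libraries, all but pre_Liver replicate 2 (adjusted p = 0.0534 to 0.145, within 0.000117 to 0.156). Cd274 (−1.15 ± 0.52), Cd8a (0.82 ± 0.50), Foxp3 (0.27 ± 0.36), Ifng (−0.18 ± 0.48), Ctla4 (0.24 ± 0.42), Arg1 (1.53 ± 0.65), Cxcl9 (0.21 ± 0.45), Cxcl10 (−0.81 ± 0.57), S100a8 (1.14 ± 0.87) and S100a9 (0.38 ± 0.74) were not called, nor were Tubb3 (−0.33 ± 0.41), Mki67 (−1.27 ± 0.66) and Cdkn1a (−0.85 ± 0.35). Without pre_Liver replicate 1, Cd274 and Cdkn1a were called (adjusted p = 0.0415 and 0.0305), and without pre_Liver replicate 2 Arg1, Mki67 and Cdkn1a (0.00808, 0.019 and 0.0375), with adjusted p over their alternatives up to 0.229, 0.266, 0.273 and 0.413 for Cd274, Cdkn1a, Arg1 and Mki67.

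In all, limma called 6704 of 13725 genes at adjusted p under 0.05, 2106 higher and 4598 lower in liver tumors, and 4345 of them differed by more than 2-fold. The groups did not overlap for 52.2% of the genes, against 3.57% by chance. The median of all genes was −0.52, and after scaling by the median of ratios it was −0.01 with 3218 genes higher and 2490 lower, while rescaling without the liver-function lists gave 2656 higher and 3059 lower. None of the called lists described here changed direction under either scaling or under quantile normalization. Within the first of the 2 batches in the authors' adjustment (3 against 3 libraries), 2021 genes were higher and 2824 lower, Alb differed by 12.37, the hepatocyte list by 9.50, glycolysis by −1.04 and hypoxia by −1.20. The second batch held liver libraries alone and gives no value. Leaving out 1 library at a time gave 3696 genes without pre_Liver replicate 3 and 2325, 3162 and 2448 without pre_SC replicates 1, 2 and 3.

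In subcutaneous tumors, paclitaxel treatment went with lower expression of glucose breakdown, low-oxygen and mitosis genes. Of 16 glycolysis genes, 13 fell, and 14 adjusted over the list alone, with a median log2 change of −1.20 (camera adjusted p = 1.27e-13, and adjusted p = 0.463 with an estimated correlation). Pgam1, a phosphoglycerate mutase, fell from 757 ± 33.2 TPM (SD, n = 3) by 1.38 ± 0.09 on the log2 scale (SE; limma adjusted p = 0.00204). The phosphofructokinases Pfkl and Pfkp and the pyruvate kinase Pkm changed by −1.73 ± 0.13, −1.31 ± 0.11 and −1.09 ± 0.09. Of 18 hypoxia genes, 8 fell, and 11 adjusted over the list alone (list median −1.09; camera adjusted p = 6.19e-08, and adjusted p = 0.463 with an estimated correlation). Among them P4ha1, a collagen prolyl hydroxylase, changed by −2.03 ± 0.13, Car9, a carbonic anhydrase induced by low oxygen, by −3.13 ± 0.35, and Slc2a1, which stands on both lists, by −1.76 ± 0.20. Of 24 cell cycle genes, 12 fell, and 19 adjusted over the list alone (list median −0.86; camera adjusted p = 5.09e-11, and adjusted p = 0.515 with an estimated correlation), such as the spindle checkpoint kinase Bub1b at −1.31 ± 0.17 and cyclin B1 (Ccnb1) at −0.94 ± 0.15.

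Among genes of inflammation in treated subcutaneous tumors, the cytokine gene Il1b changed by −2.57 ± 0.21 (limma adjusted p = 0.00506) and Nos2, the inducible nitric oxide synthase, by −2.78 ± 0.37 (limma adjusted p = 0.0135). Of 28 interferon response genes, 4 fell, and 13 adjusted over the list alone (list median −0.83; camera adjusted p = 5.09e-07, and adjusted p = 0.764 with an estimated correlation). Among them were the transcription factor Irf1 (−0.81 ± 0.13), the T cell attracting chemokine Cxcl10 (−1.34 ± 0.21) and the GTPase Igtp (−1.32 ± 0.31). Other members stood apart in post_SC replicate 2, where Ifit1 was at 223.6 TPM against 39.4 and 27.4 in the other treated and 53.5 to 85.7 in the untreated libraries, and the list median without that library was −1.19. Of 19 genes for myeloid-attracting chemokines and growth factors, 3 fell, Il1b, Ccl2 (−1.22 ± 0.22) and Csf1 (−0.98 ± 0.18), and adjusted over the list alone 6 fell and 1 rose (camera adjusted p = 0.000531, and adjusted p = 0.463 with an estimated correlation). Of 10 genes of MHC class II presentation, 3 fell, among them the transactivator Ciita (−2.08 ± 0.35), and 8 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0019, and adjusted p = 0.764 with an estimated correlation). Of 12 endothelial genes, 6 rose and 2 fell, and 9 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.000531, and adjusted p = 0.463 with an estimated correlation), with Emcn (endomucin) at 1.501 ± 0.16 and the tight junction gene Cldn5 at 1.97 ± 0.28.

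By size of change, the genes that rose most included Alox12e, a lipoxygenase, by 3.77 ± 0.58 (limma adjusted p = 0.0172), the ADP-ribosyltransferase Art2b by 3.74 ± 0.81, the trefoil factor Tff1 by 3.47 ± 0.24, the thyroid hormone deiodinase Dio2 by 3.25 ± 0.18, Depp1 by 3.07 ± 0.58 and the apolipoprotein Apoc4 by 2.998 ± 0.30. Those that fell most included the metalloproteinases Mmp13 (−4.00 ± 0.74), Mmp10 (−3.95 ± 0.65), Mmp3 (−3.75 ± 0.57) and Mmp12 (−3.65 ± 0.46; limma adjusted p = 0.0116). Mmp13 (chromosome 9, 7272514 to 7283331, GRCm38) went from 735 ± 491 TPM (SD, n = 3) to 38.9 ± 25.9 TPM (SD, n = 3). The major urinary protein genes Mup10 and Mup9 changed by −4.70 ± 0.94 and −3.76 ± 0.54, with uncertain values since the family holds near-identical copies. The calls of Tff1, Dio2 and Mmp12 held without any 1 library, and that of Apoc4 did too. Other calls ended at adjusted p = 0.0556 and 0.0599 for Alox12e without pre_SC replicates 1 and 2, 0.0893, 0.0982 and 0.0745 for Mmp13 without pre_SC 1, pre_SC 3 and post_SC 1, 0.0733 and 0.0808 for Mmp10 and 0.0676 and 0.0695 for Mmp3 without pre_SC 1 and pre_SC 3. Depp1 lost its call without pre_SC 1, 2 or 3 or post_SC 3 (0.0921, 0.093, 0.0833 and 0.066), Art2b without any 1 library but pre_SC 2 (0.06 to 0.121), Mup10 without any 1 but post_SC 2 (0.0525 to 0.0889) and Mup9 without pre_SC 1 (0.0593). Over all alternatives the adjusted p of these genes reached 0.0599 (Alox12e), 0.0982 (Mmp13), 0.0808 (Mmp10), 0.0695 (Mmp3), 0.093 (Depp1), 0.121 (Art2b), 0.19 (Mup10) and 0.0932 (Mup9), from lows of 0.0144, 0.0156, 0.0127, 0.0113, 0.00973, 0.0153, 0.0267 and 0.00958.

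Of the other genes set in advance, Tubb3, a beta tubulin of neurons and some tumors, fell from 2.06 ± 0.85 TPM to 0.113 ± 0.0557 TPM (SD, n = 3 each; log2 change −1.42 ± 0.28, limma adjusted p = 0.0327). Its call ended without pre_SC replicate 1, post_SC replicate 1 or post_SC replicate 3 (adjusted p = 0.0635, 0.0752 and 0.0618, within 0.0272 to 0.102 over its alternatives), and that of Cxcl10 without pre_SC replicates 1, 2 or 3 or post_SC replicate 1 (adjusted p = 0.0668, 0.0636, 0.0507 and 0.0531, within 0.0147 to 0.414). Cxcl9 (−1.23 ± 0.30), S100a9 (−1.79 ± 0.46), S100a8 (−1.21 ± 0.65), Gzmb (−1.48 ± 0.41), Pdcd1 (1.31 ± 0.38), Cd8a (0.77 ± 0.34), Ctla4 (0.37 ± 0.34), Ifng (−0.64 ± 0.28) and Cd274 (−0.64 ± 0.25) were not called. Nor were Arg1 (−0.10 ± 0.46), Abcb1a (0.40 ± 0.21), Abcb1b (−0.43 ± 0.21), Mki67 (−0.56 ± 0.24), Cdkn1a (−0.28 ± 0.24), Krt8 (−0.31 ± 0.12) and Alb (0.02 ± 0.50). Without pre_SC replicate 1, S100a8 (−2.07) and S100a9 (−2.36) were called, each at adjusted p = 0.0363, within 0.0363 to 0.657 and 0.0363 to 0.414 over their alternatives. The score of the neutrophil list differed by −0.74, which the library-level test did not call (exact permutation p = 0.3, and 0.548 after adjustment). Camera called the list lower, with 1 of 17 genes called, Il1b, and 2 adjusted over the list alone (list median −0.64; camera adjusted p = 0.0319, and adjusted p = 0.764 with an estimated correlation). That call ended without pre_SC replicate 2 or post_SC replicate 2 (medians of −0.59 and −0.61, adjusted p = 0.317 and 0.0948, within 2.17e-05 to 0.764 over its alternatives).

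Skeletal muscle transcripts were high in 1 treated library. Acta1, skeletal muscle actin, stood at 3226 TPM in post_SC replicate 2 and at 0.427 to 181.2 TPM in the other 5 subcutaneous libraries. None of the 13 muscle genes was called over all genes or adjusted over the list alone, while the list was called (median 2.42; camera adjusted p = 0.00267, and adjusted p = 0.827 with an estimated correlation). Without that library the muscle list was not called (median 1.09, adjusted p = 0.124, within a range reaching 0.827 over its alternatives), and the glycolysis list stayed lower with a median of −1.24.

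Over all genes, limma called 930 of 13365 in the subcutaneous response, 357 that rose and 573 that fell, and 401 changed by more than 2-fold. The groups did not overlap for 34.7% of genes, against 10% by chance. Leaving out pre_SC replicate 1, 2 or 3 or post_SC replicate 1 gave 77, 192, 93 and 388 genes. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1, the value the glycolysis list score reached (difference −1.11).

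**Figure D2:**
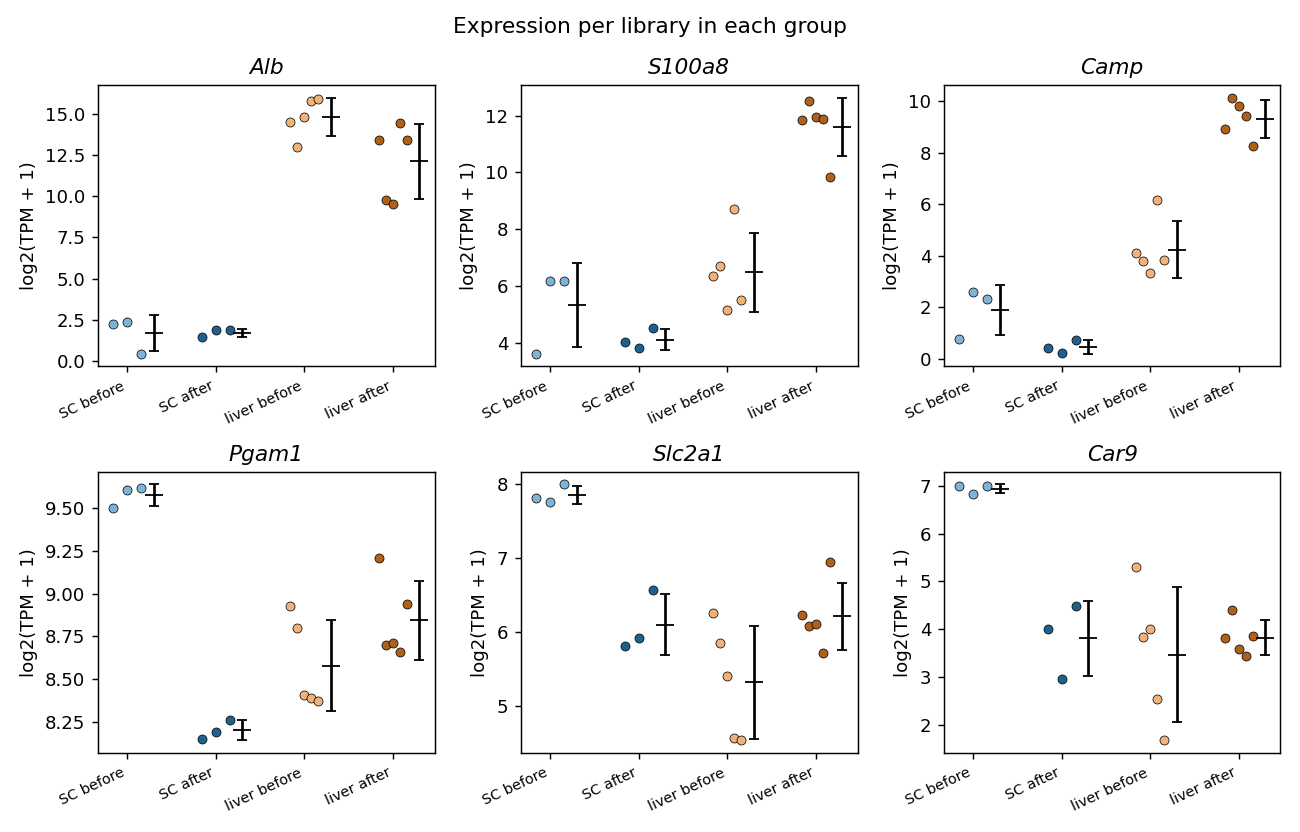
Each point is 1 library, in log2(TPM + 1) over the genes shared by the tables, for Alb, S100a8, Camp, Pgam1, Slc2a1 and Car9 in the 4 groups (3 libraries per subcutaneous and 5 per liver group), with the mean and SD of each group beside the points. Camp averaged 4.24 ± 1.11 (SD) in liver tumors before and 9.31 ± 0.74 after treatment, and Car9 6.94 ± 0.09 and 3.81 ± 0.78 in subcutaneous tumors.

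In liver tumors, paclitaxel treatment went with a rise of neutrophil genes. Of 20 genes on the neutrophil list, 17 rose, also 17 adjusted over the list alone, with a median log2 change of 3.28 (camera adjusted p = 3.35e-11, and adjusted p = 0.473 with an estimated correlation). S100a8 (chromosome 3, 90668978 to 90670035, GRCm38) and S100a9, the subunits of the calcium-binding protein calprotectin, rose by 5.12 ± 0.68 and 4.88 ± 0.72 (SE; limma adjusted p = 0.00576 and 0.00783). S100a8 averaged 69.7 ± 79.7 FPKM (SD, n = 5) before and 1933 ± 965 FPKM (SD, n = 5) after treatment. Camp and Ngp, which encode the granule proteins cathelicidin and neutrophilic granule protein, rose by 4.99 ± 0.52 and 5.33 ± 0.64, the stefin Stfa2 by 5.71 ± 0.61, Elane (neutrophil elastase) by 4.66 ± 0.58, Cd177 by 4.40 ± 0.51 and Ly6g by 2.35 ± 0.42 (limma adjusted p = 0.0172). Stfa2 belongs to a family of near-identical copies and is uncertain. The hepatocyte list had a median of −2.31, and with its mean as a covariate the neutrophil median was 2.74 and S100a8 stayed called at 4.64, while S100a9 at 3.87 had adjusted p = 0.0503, within 0.000185 to 0.0503 over its alternatives.

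Some other blood cell lists rose with them, and their rise was not tested apart from that of the neutrophil genes. Other lists did not rise with them, such as B cells (median −0.52), dendritic cells (−0.32), T cells (−0.16) and erythroid cells (0.14). Camera called the B and T cell lists lower relative to the other genes. Both calls ended without pre_Liver replicate 1 (camera adjusted p = 0.129 and 0.0825), and that of T cells also without post_Liver replicate 3 (0.0635). The carboxypeptidase Cpa3 rose by 2.21 ± 0.24 and the basophil protease Mcpt8 by 2.07 ± 0.39. Of 9 mast cell and basophil genes, 6 rose, and 8 adjusted over the list alone (camera adjusted p = 9.25e-05, and adjusted p = 0.473 with an estimated correlation). Gp1bb and Gp9 of the von Willebrand factor receptor rose by 1.20 ± 0.15 and 1.25 ± 0.20, and the platelet chemokine Pf4 by 1.42 ± 0.24. Of 6 platelet genes, 5 rose, also 5 adjusted over the list alone (camera adjusted p = 0.0058, and adjusted p = 0.555 with an estimated correlation). Of 10 monocyte genes, 3 rose, among them Chil3 (4.61 ± 0.43) and F13a1 (1.74 ± 0.37), and 5 adjusted over the list alone (camera adjusted p = 0.0421, and adjusted p = 0.794 with an estimated correlation). The NADPH oxidase subunit Ncf1 rose by 1.95 ± 0.26. Of 16 genes of myeloid suppressor effectors, 6 rose, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0443, and adjusted p = 0.781 with an estimated correlation). The platelet call ended without pre_Liver replicate 2 or post_Liver replicate 4 (adjusted p = 0.0899 and 0.0821). The monocyte call ended without pre_Liver 2 or post_Liver 1, 4 or 5 (adjusted p = 0.0904, 0.0582, 0.172 and 0.054), and that of the suppressor effectors without pre_Liver 2 or post_Liver 1 or 4 (adjusted p = 0.261, 0.0549 and 0.147). Over their alternatives adjusted p reached 0.555, 0.794 and 0.781.

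Of 30 hepatocyte genes, 2 fell, Mup3 (−5.65 ± 0.70) and the fatty acid binding protein Fabp1 (−4.995 ± 0.69), and 10 adjusted over the list alone, with a list median of −2.31 (camera adjusted p = 2.74e-19, and adjusted p = 0.538 with an estimated correlation). By the exact two-sided permutation test the hepatocyte list score differed by −2.48, with p = 0.0476 and 0.218 after adjustment. G6pc and Cyp7a1, enzymes of glucose release and bile acid synthesis, stood at −3.95 ± 0.98 and −2.80 ± 0.80 and were not called. The largest falls were of the major urinary protein genes, Mup9 (−9.23 ± 0.73), Mup2 (−7.13 ± 1.12), Mup19 (−7.00 ± 1.34), Mup16 (−6.82 ± 1.15), Mup10 (−6.68 ± 1.19) and Mup12 (−6.28 ± 1.00; limma adjusted p = 0.0104), whose near-identical sequences make the split between them uncertain. Of 16 paclitaxel disposition genes, 3 fell, the carrier Slco1a1 (−2.86 ± 0.40) and the cytochromes Cyp2c37 (−4.29 ± 0.97) and Cyp2c29 (−4.29 ± 1.03), and 9 adjusted over the list alone (camera adjusted p = 2.62e-09, and adjusted p = 0.473 with an estimated correlation). Of 20 genes of fatty acid and lipid metabolism, 3 fell, and 18 adjusted over the list alone (camera adjusted p = 7.87e-16, and adjusted p = 0.473 with an estimated correlation). Without any 1 of the libraries named here, the calls of Mup10 (pre_Liver 3 and 5, post_Liver 1 and 2, adjusted p = 0.0602, 0.0533, 0.0633 and 0.0502), Mup16 (pre_Liver 3, 0.0507) and Mup19 (pre_Liver 3 to 5 and post_Liver 1 to 3, 0.0512 to 0.073) ended. Their adjusted p reached 0.156, 0.133 and 0.193 over all alternatives.

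Among the genes set in advance, Alb (−2.69 ± 1.03, limma adjusted p = 0.121), Cyp3a11 (−1.77 ± 0.74), Krt8 (0.90 ± 0.30), Mki67 (1.20 ± 0.54) and Cdkn1a (1.02 ± 0.40) were not called. Neither were the lymphocyte and checkpoint genes Cd274 (−0.16 ± 0.49), Pdcd1 (0.41 ± 0.46), Ctla4 (−0.10 ± 0.39), Cd8a (0.10 ± 0.48), Gzmb (0.42 ± 0.49) and Ifng (−0.17 ± 0.39), nor Arg1 (−0.20 ± 0.59), Cxcl9 (−0.83 ± 0.50), Cxcl10 (0.19 ± 0.56), Abcb1a (−0.58 ± 0.28) and Abcb1b (0.53 ± 0.34). Without pre_Liver replicate 2, Cyp3a11 (adjusted p = 0.0393), Krt8 (0.0261) and Mki67 (0.0377) were called, within ranges of 0.00635 to 0.848, 0.0012 to 0.512 and 0.0111 to 0.87 over their alternatives. The call of Ly6g ended without pre_Liver replicate 3 or 5 (adjusted p = 0.06 and 0.0533, within 0.000641 to 0.103).

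In the liver response limma called 474 of 13008 genes, 291 that rose and 183 that fell, and 366 changed by more than 2-fold. The groups did not overlap for 6.63% of genes, against 0.794% by chance. The median of all genes was 0.37, and 0.03 after scaling by the median of ratios, which gave 221 calls, 198 of them among the 474. The count moved to 3532, 117, 173 and 140 without pre_Liver replicates 2, 3, 4 and 5 and to 130, 134, 173, 1800 and 286 without post_Liver replicates 1 to 5. Against the first batch of untreated libraries alone (without pre_Liver 4 and 5) 78 genes were called and the neutrophil median was 3.32, and against the second (without pre_Liver 1 to 3) 6062 and 2.999. No batch is given for the treated libraries. By the exact permutation test the neutrophil list score rose by 3.11 with p = 0.00794, the smallest that arrangements of 5 against 5 libraries can give, and p = 0.0873 after adjustment over 55 lists.

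The responses at the 2 sites differed in neutrophil, glycolysis and hypoxia genes. In 1 limma fit of all 16 libraries, the change in liver tumors minus that in subcutaneous tumors was 6.68 ± 1.06 (SE) on the log2 scale for S100a9 (limma adjusted p = 0.00682), 6.66 ± 1.19 for Ngp, 6.51 ± 0.82 for Camp, 6.402 ± 1.19 for Stfa2, 6.38 ± 1.48 for Stfa3 and 6.35 ± 1.10 for S100a8. Of 20 neutrophil genes, 14 differed in this direction, and 17 adjusted over the list alone (list median 3.25; camera adjusted p = 3.39e-12, and adjusted p = 0.61 with an estimated correlation). Of 16 glycolysis genes, 8 differed, and 15 adjusted over the list alone (list median 1.67; camera adjusted p = 3.8e-08, and adjusted p = 0.622 with an estimated correlation), with Pgam1 at 1.64 ± 0.25, Pfkl at 2.23 ± 0.36 and the lactate transporter Slc16a3 at 2.70 ± 0.48. Of 18 hypoxia genes, 5 differed, and 10 adjusted over the list alone (list median 1.06; camera adjusted p = 0.000222, and adjusted p = 0.622 with an estimated correlation), such as P4ha1 at 2.77 ± 0.44. Without pre_Liver 4 and 5 the glycolysis median was 1.15 and the hypoxia median 0.79. Of 16 carcinoma epithelium genes, 1 differed, also 1 adjusted over the list alone, and the list was not called (median 1.55; camera adjusted p = 0.0653, within 0.00169 to 0.913 over its alternatives). It was called without pre_Liver 1 or 2, post_Liver 4 or post_SC 3 (adjusted p = 0.0352, 0.0438, 0.0126 and 0.0436). Its median was near that of glycolysis and above that of hypoxia. A changed share of carcinoma RNA in the liver libraries was not tested for the glycolysis and hypoxia differences. Site and the number of implanted cells cannot be told apart in the difference of responses either.

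Of 10 mast cell and basophil genes, 3 differed toward liver tumors, with Mcpt8 at 5.22 ± 0.66, and 4 adjusted over the list alone (camera adjusted p = 0.00132, and adjusted p = 0.643 with an estimated correlation). The platelet chemokine gene Pf4, which fell in subcutaneous (−3.02 ± 0.45) and rose in liver tumors (1.42 ± 0.24), differed by 4.52 ± 0.52 (limma adjusted p = 0.00106). Genes with a lower change in liver tumors were led by the methyltransferase Inmt (−6.05 ± 1.38), Mup9 (−5.86 ± 1.22), Mup3 (−5.40 ± 0.99), Depp1 (−5.23 ± 0.76), the cytochrome Cyp3a44 (−5.08 ± 1.16) and Apoc4 (−5.04 ± 1.13). Inmt, Mup3 and Cyp3a44 averaged at most 1.25 TPM in either subcutaneous group, so their differences rest mainly on the liver change. Of 12 endothelial genes, Cldn5 alone differed (−2.19 ± 0.46), and 7 adjusted over the list alone (list median −1.41; camera adjusted p = 2.61e-07, and adjusted p = 0.622 with an estimated correlation). Of 29 hepatocyte genes, 2 differed, also 2 adjusted over the list alone (list median −2.36; camera adjusted p = 3.39e-12, and adjusted p = 0.622 with an estimated correlation). The calls of Inmt and Cyp3a44 ended without any 1 of pre_Liver 3 to 5, post_Liver 1 or 2 or the 6 subcutaneous libraries (adjusted p = 0.0518 to 0.0891 and 0.0512 to 0.0947), and that of Apoc4 without any 1 of the same libraries other than post_Liver 2 (0.0513 to 0.0947). That of Stfa3 ended without any 1 of pre_Liver 3 to 5, post_Liver 1 to 3, pre_SC 3 or post_SC 1 to 3 (0.0509 to 0.0792). Without pre_SC 3, which held most of its subcutaneous RNA before treatment, the difference for Stfa3 was 4.56. Over all alternatives their adjusted p reached 0.103, 0.103, 0.0998 and 0.101. Mup9 lost its call without pre_SC replicates 1 or 2 or post_SC replicates 1 or 3 (adjusted p = 0.0622, 0.0709, 0.0542 and 0.0573, within a range reaching 0.188).

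**Figure D3:**
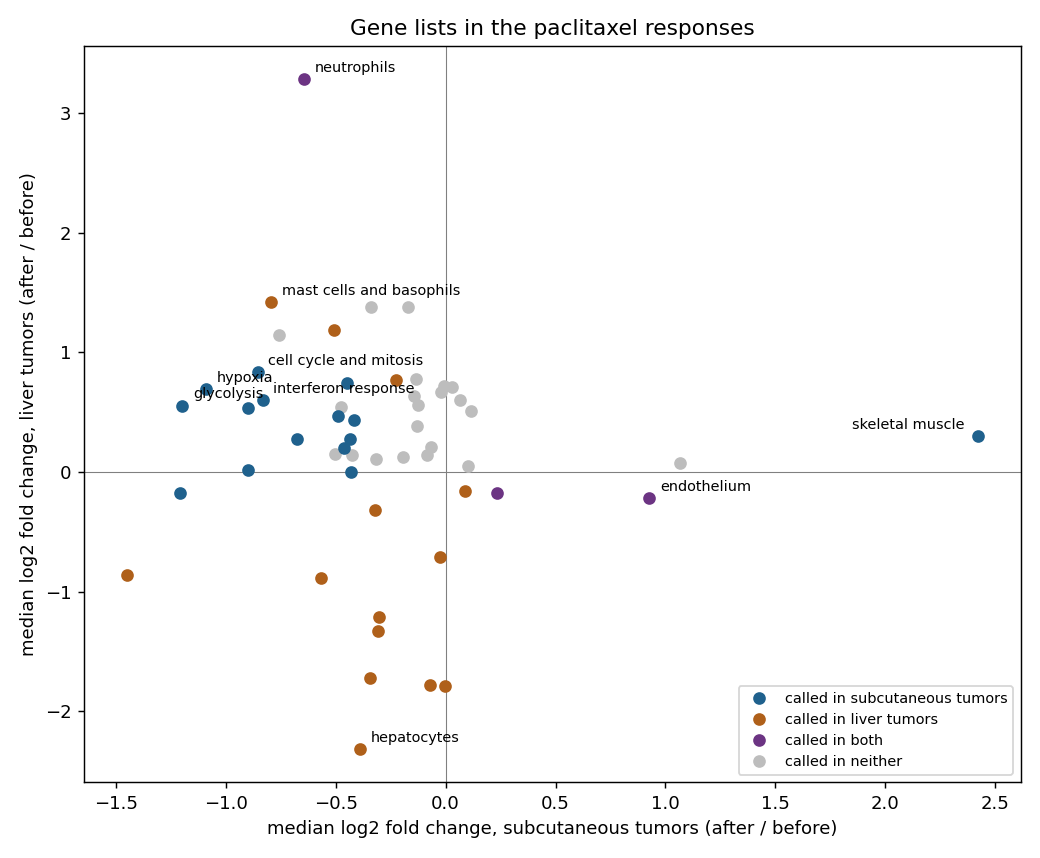
Each point is 1 of the 53 gene lists tested at both sites, with its median log2 change after treatment in subcutaneous tumors (3 against 3 libraries) on the horizontal axis and in liver tumors (5 against 5) on the vertical axis, colored by the site at which camera called it. Neutrophil genes lie at −0.64 and 3.28, glycolysis at −1.20 and 0.56, and hepatocytes at −0.39 and −2.31.

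The difference of the responses was called by limma for 415 of 13698 genes, 306 with a higher and 109 with a lower change in liver tumors, and 397 differed by more than 2-fold. Scaling by the median of ratios moved the median of all genes from 0.39 to −0.03. It gave 321 calls, 225 of them among the 415, and 58.3% were higher against 73.7%. Quantile normalization gave 372 calls, 271 of them among the 415, and 62.6% were higher. No called list named here changed direction under these scalings. The count was 2597, 169, 219 and 211 without pre_Liver replicates 2 to 5, 190, 246, 273 and 916 without post_Liver replicates 1 to 4, 141, 133 and 91 without pre_SC replicates 1 to 3, and 147, 256 and 159 without post_SC replicates 1 to 3.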

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

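The tests of regrouped libraries were fixed before the results were seen, and the tests below of neutrophil and glycolysis genes were chosen after.

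In the treated liver tumors, post_Liver replicate 5 had the lowest values of several neutrophil genes and the highest of Cd8a, the CD8 chain of cytotoxic T cells. Its Ngp stood at 9.04 in log2(FPKM + 1) against a group median of 10.66, S100a8 at 8.88 against 10.94 and Elane at 6.13 against 7.83, with gaps to the nearest library of 0.714, 0.73 and 0.739 as a share of the group's range. Its Cd8a stood at 4.71 against 3.02 (share 0.727), and its dendritic cell score at 0.38 against −0.20 (share 0.89). Among untreated liver tumors, pre_Liver replicate 4 had the highest Camp, at 5.18 against 2.996 (share 0.722), and pre_Liver replicate 2 the lowest major urinary protein genes, with Mup9 at 8.53 against 11.08 (share 0.752), Mup2 at 9.63 against 11.93 (share 0.781) and Mup10 at 9.62 against 12.00 (share 0.764). These were 9 of 128 groups of values tested, by a test that marks about 1 group in 20 by chance.

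The responses of the 2 sites differed for 415 genes. Among named genes the change in liver tumors minus that in subcutaneous tumors was 6.68 for S100a9, 6.66 for Ngp, 6.51 for Camp, 6.402 for Stfa2, 6.38 for Stfa3 and 6.35 for S100a8 on the log2 scale. It was −6.05 for Inmt, −5.86 for Mup9, −5.40 for Mup3, −5.23 for Depp1, −5.08 for Cyp3a44 and −5.04 for Apoc4.

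By list medians, the difference was above 0 for neutrophils (3.25), mast cells and basophils (2.92), cell cycle and mitosis (1.77), monocytes (1.73), glycolysis (1.67), interferon response (1.47), myeloid-attracting chemokines (1.44), myeloid suppressor effectors (1.35), DNA replication (1.17), hypoxia (1.06), DNA repair (1.06) and platelets (1.01). It was below 0 for hepatocytes and skeletal muscle (−2.36 each), paclitaxel disposition and xenobiotic metabolism (−1.92 each), complement and coagulation (−1.71), endothelium (−1.41), acute phase response (−1.13), fatty acid oxidation (−1.07), Kupffer cells (−0.63), stellate cells (−0.52), oxidative phosphorylation (−0.40), B cells (−0.36), T cells (−0.23) and sinusoidal endothelium (−0.23). No list kept its call with an estimated correlation. The muscle value rested largely on post_SC replicate 2 and was −0.97 without it.

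Several of these list calls ended when 1 library was left out. Sinusoidal endothelium stood at 0.062 and 0.19 without post_Liver replicates 2 and 3 (adjusted p = 0.116 and 0.115), stellate cells at −0.52 and −0.56 (0.0768 and 0.0691), and Kupffer cells at −0.47 and −0.42 (0.0768 and 0.0787) and at −0.84 without pre_SC 1 (0.111). B cells lost their call without pre_Liver 1 or post_Liver 2 (0.0524 and 0.066). T cells stood at 0.0025 without post_SC 2 (0.161) and also lost their call without pre_Liver 1 or 3, post_Liver 2 or 3 or pre_SC 3 (0.114, 0.0687, 0.116, 0.133 and 0.0568). Monocytes lost theirs without pre_Liver 2 or post_Liver 4 (0.0685 and 0.0779), suppressor effectors without pre_Liver 2 (0.0985), platelets without post_Liver 4 (0.0554) and DNA replication without post_SC 2 (0.0583). Myeloid-attracting chemokines lost theirs without pre_Liver 2, post_Liver 4 or 5, pre_SC 2 or 3 or post_SC 2 (0.102, 0.0598, 0.0665, 0.0694, 0.0702 and 0.0616).

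Regrouping the libraries tested whether other groupings call as many genes. Before treatment 2 of 56 splits called as many genes as the real one, itself included, with 6704 in the real split and 9379 in the highest other, which set pre_Liver replicates 1 and 2 with the 3 subcutaneous libraries. In the liver response 3 of 100 drawn splits did, with 474 in the real split and 8009 in the highest other, which set pre_Liver replicates 1, 3, 4 and 5 with post_Liver replicate 4. In the difference 1 of 100 drawn splits did, the real one with 415 genes against 58 in the highest other. In the subcutaneous response, with 930 genes in the real split and 0 in the highest other, 1 of 10 did, and 10 splits are too few to tell.

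Neutrophil genes rose in liver tumors where the hepatocyte list had a median of −2.31 with 2 of 30 genes called. A smaller share of hepatocyte RNA alone would raise all other cell types alike. A smaller share of liver tissue need not raise Kupffer, sinusoidal or stellate cells, which are among these lists. The median over the other cell type lists was 0.15, under the bound of 1.58 set by the spread of the neutrophil genes. The lists of liver-resident cells pull that median down, but the highest other list, at 1.42, was also under the bound. A smaller hepatocyte share therefore does not account for the whole rise. The other lists moved apart, from −0.88 for Kupffer cells and −0.71 for sinusoidal endothelium to 1.42 for mast cells and basophils. Monocytes stood at 1.19, platelets at 1.23 and carcinoma and biliary epithelium at 1.38 each, against 3.28 for neutrophils. The carcinoma and biliary lists may hold the same signal, and a part of the rise stays open. The mix of untreated batches does not account for it, as the lower of the neutrophil medians against each batch was 2.999. Tumor age, a batch of the treated libraries and a change in the neutrophils themselves were not tested apart from treatment.

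Glycolysis genes fell in subcutaneous tumors. The carcinoma epithelium median was −0.17, above the bound of −0.74 set by the spread of the glycolysis genes. As far as that list follows the share of carcinoma cells, a smaller share does not account for the whole fall. Whether its genes follow that share was not tested. Tumor age and a batch of the treated libraries were not tested apart from treatment.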

How the results depend on the processing

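Most analyses below were fixed before the data were examined, while those by batch, without the close library pair, on values as deposited, on TPM over shared genes and by separate fits were chosen after.

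Before treatment, array weights gave 11305 genes without converging and a bound of at least 2-fold gave 4345. Leaving out 1 library gave 2325 to 9488. The values as deposited gave 7851 with those below 0 set to 0 and 8148 on the linear scale, and batch as a covariate 6093. TPM over shared genes gave 919 in the subcutaneous and 432 in the liver response. For the subcutaneous response at least 2-fold gave 401, a shared fit of all 4 groups 124, and leaving out 1 library 77 to 774. For the liver response the median of ratios gave 221, at least 2-fold 366, the shared fit 2716, array weights 7257 without converging, and the hepatocyte covariate 297. Without post_Liver 2 and 3 it was 139, without pre_Liver 4 and 5 it was 78, and without pre_Liver 1 to 3 it was 6062. Leaving out 1 library gave 117 to 3532. For the difference array weights gave 6555 without converging, the separate fits 3193, and the fit without pre_Liver 4 and 5 gave 156. The separate fits were compared by a normal z, which gives a lower p than a moderated t of the same size. Their count is therefore not like for like with the 415 of the main fit. Leaving out 1 library gave 91 to 2597. Otherwise the cause of these changes in count was not tested.

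With replicate numbers as a block, the counts were 3781 before treatment, 330 in the subcutaneous response, 3456 in the liver response and 1427 in the difference. The labels do not say that numbers pair the libraries. Correlations of matching numbers were 0.12, −0.12 and −0.12 in subcutaneous tumors, −0.12, 0.69, 0.02, 0.76 and 0.26 in liver tumors and 0.01, −0.09 and −0.04 before treatment. The best match carried the same number for pre_SC replicate 1 and pre_Liver replicate 4 across treatment, and another number for the rest. Hepatocyte RNA varied widely among the liver libraries, so these correlations neither show nor exclude pairing.

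With an estimated correlation 0 lists were called in each of the 4 comparisons. The rotation test fry called 19 lists before treatment, 10 in the subcutaneous response, 8 in the liver response and 8 in the difference.

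List directions are relative to the other genes. With the hepatocyte covariate the direction in the liver response reversed for hepatocytes (0.14), a value near 0 by construction since the covariate is the mean of that list. It also reversed for Kupffer cells (0.17), sinusoidal endothelium (0.52), endothelium (0.30), fibroblasts and matrix (0.73), stellate cells (0.39), T cells (0.054), B cells (0.017), alternatively activated macrophages (0.85), acute phase response (0.80), complement and coagulation (0.21), xenobiotic metabolism (0.17), epithelial-mesenchymal transition (0.39) and unfolded protein response (0.50). Without post_Liver 2 and 3 it reversed for sinusoidal endothelium (−0.0059), endothelium (0.17) and fibroblasts and matrix (0.77), and in the difference for sinusoidal endothelium (0.61), fibroblasts and matrix (1.11) and macrophages (1.06). Without pre_Liver 4 and 5 it reversed for interferon response (−0.056) in the liver response. The cause was not tested.

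Count-based tests were not run and do not apply, as the values are not counts.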

Other observations

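The tests of the untreated table in the last paragraph were chosen after the result was seen, and no other test was added here. Before treatment, liver tumors were lower in TGF-beta signalling genes, with 12 of 17 lower and 14 adjusted over the list alone, including Ltbp2, a binding protein of latent TGF-beta, at −2.65 ± 0.37 (SE; limma adjusted p = 0.00114), and the list at camera adjusted p = 0.00694, or adjusted p = 0.847 with an estimated correlation. Of 23 ribosomal protein genes, 12 were lower, and 21 adjusted over the list alone, with Rpl3 at −1.48 ± 0.44 (camera adjusted p = 0.0138, and adjusted p = 0.847 with an estimated correlation). Of 10 mast cell and basophil genes, 7 were lower, also 7 adjusted over the list alone, with the tryptase Tpsb2 at −3.92 ± 0.50 (camera adjusted p = 0.0272, and adjusted p = 0.847 with an estimated correlation), a call that ended without pre_Liver replicate 2 (adjusted p = 0.154) or pre_SC replicate 3 (0.05). Fatty acid genes were higher, 13 of 20 with 1 lower, the same adjusted over the list alone (camera adjusted p = 1.32e-08, and adjusted p = 0.546 with an estimated correlation), and so were 4 of 4 erythroid genes, also 4 adjusted over the list alone (camera adjusted p = 0.00644, and adjusted p = 0.64 with an estimated correlation). Of 14 T cell genes, 2 were higher and 1 lower, the same adjusted over the list alone, with the kinase Zap70 at 1.81 ± 0.26 and Thy1 at −2.10 ± 0.46 (camera adjusted p = 0.00191, and adjusted p = 0.847 with an estimated correlation). Of 21 oxidative phosphorylation genes, 6 were higher, and 5 adjusted over the list alone (camera adjusted p = 0.0009, and adjusted p = 0.221 with an estimated correlation).

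In treated subcutaneous tumors, 5 of 17 unfolded protein response genes fell, and 9 adjusted over the list alone, such as the chaperones Hspa5 (−0.67 ± 0.10) and Calr (−0.88 ± 0.13; limma adjusted p = 0.0169; camera adjusted p = 0.000822, and adjusted p = 0.463 with an estimated correlation). The p53 targets Trp53inp1, Sesn1 and Pmaip1 rose by 2.08 ± 0.32, 1.16 ± 0.20 and 1.02 ± 0.20, 3 of 18 on a list that was not called (3 adjusted over the list alone; camera adjusted p = 0.154). Of 22 DNA replication genes, 2 fell, and 8 adjusted over the list alone, with the helicase subunit Mcm5 at −0.78 ± 0.14 (camera adjusted p = 0.000201, and adjusted p = 0.764 with an estimated correlation). Of 13 MHC class I genes 1 fell, and 8 adjusted over the list alone (camera adjusted p = 0.000625, and adjusted p = 0.463 with an estimated correlation). In treated liver tumors the Kupffer cell receptor Timd4 changed by −1.60 ± 0.38, 1 of 10 on its list, also 1 adjusted over the list alone (camera adjusted p = 9.25e-05, and adjusted p = 0.759 with an estimated correlation). None of 21 oxidative phosphorylation genes was called there, also 0 adjusted over the list alone (median −0.18; camera adjusted p = 7.43e-06, and adjusted p = 0.473 with an estimated correlation).

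The responses at the 2 sites shared few genes. Of 12149 genes tested in both, 6 rose in both against 6.76 expected if independent, 7 fell in both against 4.45, 6 fell in subcutaneous and rose in liver tumors against 11.5, and 2 did the reverse against 2.62. Across genes, which are not independent replicates, the changes correlated at r = −0.0091.

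In the untreated table liver genes stood high in subcutaneous libraries, with Alb deposited at 19202 in pre_SC replicate 1 and 3.90 once the batch constant of 19198.1 was removed. A linear batch adjustment by the authors fits, with a largest residual of 7.8e-06 within a batch. Liver RNA in those libraries does not, as the highest Alb value of the untreated libraries in the subcutaneous table was 4.21 TPM.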
